A study of Homo sapiens with 9 samples.

How the data were processed

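RNA from human adipose-derived stem cells was measured on Illumina bead arrays 2 days after transfection with control, KLF2 or KLF8 siRNA, with biotin-labelled cRNA per the labels' protocols. Groups and replicate numbers were taken from the sample titles, with 3 arrays in each of 3 groups. The authors deposited the mean bead signal of each probe as an intensity that was not normalized between arrays, per the file headers. Beside it the deposited table gives a detection p-value of each probe against the negative control beads of the array. A further table holds log2 values that the authors normalized. In that deposited log2 table the sorted values of all arrays differed by at most 0.000646, as after quantile normalization, and each column had the rank order of its non-normalized column. GenomeStudio and lumi are named in the submitters' processing notes, without versions, and the background step before the log2 table is not given in the sources used here. The value table of the series was identical to the normalized table (largest difference 0). The array chip of each sample is not given in the sources used here, and 0 columns of values were left unused.

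Probes were named from the platform annotation, and symbols were updated through the Entrez identifier with a gene table of assembly GRCh38.p14, which matched 29929 of 29968 probes. Of 47226 probes, 30111 had 1 gene symbol, 8 had several and 17107 had none listed; genes on the Y chromosome and XIST (143 probes) were left out. The signal was corrected by normexp with negative controls inferred from the detection p-values, with an offset of 16, and quantile normalized (neqc in limma 3.58.1, R 4.3.3). Probes detected at p under 0.05 on at least 3 arrays were kept, 21287 in all, and each gene was represented by its brightest kept probe, which left 12030 genes. In 3212 genes more than 1 probe was kept, and disagreement in sign is stated for the genes taken by the rule given below. It was not examined for ATF4 or for genes named only under other observations.

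A limma model with a mean per group over all 9 arrays, so that the groups share 1 estimate of the spread, gave log2 differences with moderated tests, and p-values were adjusted by Benjamini-Hochberg over genes at a threshold of 0.05. Gene lists, 43 in all, were written before the data were examined, and the 41 with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison. The correlation was also estimated from the data, and fry, which does not compare a list with other genes, was run beside it. The genes named were fixed by a rule before the data were examined. It took KLF2 and KLF8, the 10 genes that rose most and the 10 that fell most among those past the threshold whose 3 knockdown arrays lay beyond the 3 control arrays, leaving out provisional symbols, the 4 members with the lowest p of each shifted list and the 2 of each other list with a changed member, and 5 in each direction for the direct comparison. Not all genes taken by the rule are printed. Arrays were also compared for pairing by replicate number, and the model has no such term.

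The fit was tested on simulated data for 12030 genes. For KLF2 siRNA against control siRNA, 66 of 66 simulated genes changed by 2 on the log2 scale were recovered, 53 of 67 changed by 1 and 12 of 67 changed by 0.5, with 3 of 11830 unchanged genes called. Genes were simulated independently, and far fewer were changed than the 2492 called in the real comparison. These counts of recovered genes need not hold for the real data. Alternatives were the authors' normalized table, median scaling, no background correction, other detection filters, the mean of a gene's probes, only the 2 groups compared, intensity trend with robust spread, array quality weights, a replicate block, each array left out in turn, a 2-fold threshold and the other set tests.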

Results

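Gene expression was measured in human adipose-derived stem cells, the stromal cells of fat tissue that can become fat, bone and cartilage cells. The cells were purchased primary cells, and were transfected with a control siRNA, with KLF2 siRNA or with KLF8 siRNA. A small interfering RNA (siRNA) directs the degradation of the transcript it matches, and KLF2 and KLF8 encode zinc finger transcription factors of the Kruppel-like family. RNA was collected 2 days after transfection and hybridised to Illumina bead arrays, with 3 arrays per group and 9 in all. Between 18923 and 21170 of 47226 probes were detected per array, and the 95th percentile of signal lay 49.9 to 83.0 times above the level of the negative control beads. After probes that were detected on fewer than 3 arrays had been left out, 12030 genes were tested. Arrays of a group correlated at 0.982 to 0.992 across genes, against 0.963 to 0.985 between groups. The number of arrays limits the precision, and since nothing in the labels says that the 3 samples of a group came from separate cultures, p-values measure the spread between these samples, which may be technical.

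The first question was whether each siRNA lowered its target. KLF2 (Entrez gene 10365) fell 3.24-fold with KLF2 siRNA, from a normalized log2 signal of 12.49 ± 0.21 (SD, n = 3) with control siRNA to 10.80 ± 0.21 (SD, n = 3), with a limma adjusted p = 0.000223. All 3 KLF2 siRNA arrays lay below all 3 control arrays, and 30.9% of the control signal remained. With KLF8 siRNA the KLF2 signal was 12.92 ± 0.26 (SD, n = 3), and its difference of 0.42 from control did not pass (adjusted p = 0.25). KLF8 (Entrez gene 11279) has 1 probe on the array. That probe was detected on 0 of 9 arrays, with a lowest detection p of 0.0584, on KLF8 siRNA array 1. Its undetected signal was 6.51 ± 0.66 with KLF8 siRNA and 5.93 ± 0.12 with control siRNA (SD, n = 3), a difference that did not pass (limma adjusted p = 0.346). The level of KLF8 transcript, and its knockdown, could therefore not be read from these arrays.

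**Figure D1:**
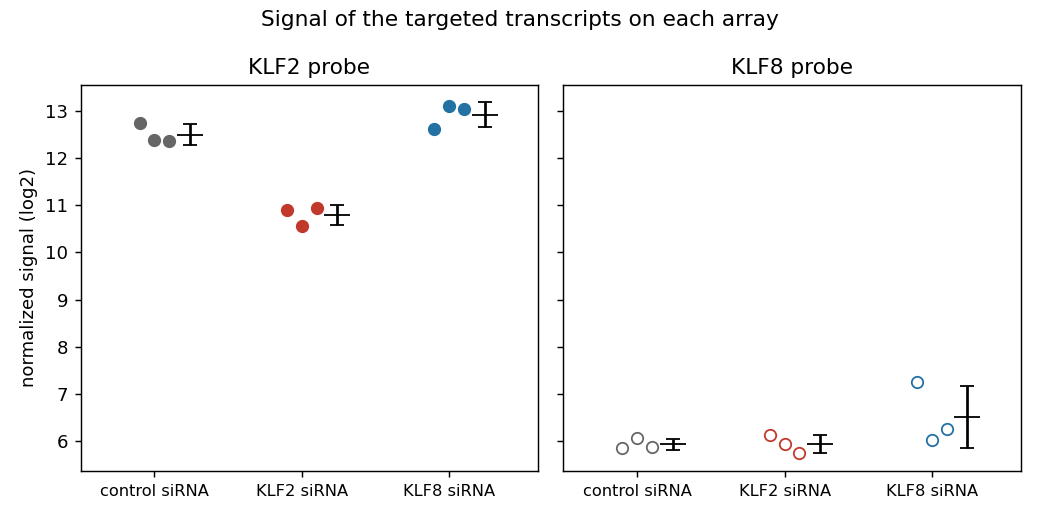
Normalized log2 signal (vertical axis) of the KLF2 probe (left) and the KLF8 probe (right) on each of the 9 arrays, by siRNA group (horizontal axis). Filled points are detected at p under 0.05 and open points are not; the bar beside them is the mean with SD of 3 arrays. The KLF2 probe sits at 10.80 on average with KLF2 siRNA against 12.49 with control siRNA, while the KLF8 probe is open on all arrays.

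The comparison of KLF2 siRNA with control siRNA asked which genes differ after KLF2 siRNA in these cells. Such changes may include effects of the siRNA itself as well as of the loss of KLF2. Of 39 NF-kB and inflammatory mediators 19 rose and 1 fell, and of 27 amino acid starvation response genes 17 fell and 0 rose, and both lists also passed with an estimated correlation. Of 52 interferon response genes 39 rose and 2 fell (list adjusted p = 0.137 with an estimated correlation). Of 12030 genes, 2492 changed at an adjusted p under 0.05, 1312 higher and 1180 lower, and 584 of them changed at least 2-fold (348 higher, 236 lower). In 39.7% of genes the 3 KLF2 siRNA arrays did not overlap the 3 control arrays, against 10% by chance. NPTX1, a neuronal pentraxin detected on 2 of 3 control arrays, rose most, 19.3-fold (log2 11.57 ± 0.05 against 7.30 ± 0.44, SD, n = 3; adjusted p = 8.16e-06). HERC5, the ligase that attaches ISG15 to proteins, rose 17.6-fold (12.23 ± 0.34 against 8.09 ± 0.38; adjusted p = 1.92e-05), and the chemokine gene CCL7 rose 12.6-fold (12.55 ± 0.13 against 8.90 ± 0.15; adjusted p = 1.73e-06). F13A1, the catalytic subunit of coagulation factor XIII, was not well above background on any control array and rose at least 4.66-fold. Such a bound sets the mean of the brighter group against the mean, per array, of the higher of the dim probe's signal and the lowest signal among detected probes. The neurotensin receptor gene NTSR1 (8.87-fold), KYNU of tryptophan breakdown (8.67-fold), the RNA-binding protein gene IGF2BP3 (8.14-fold), OAS2 (7.86-fold), the chemokine gene CCL8 (7.63-fold) and the apolipoprotein gene APOD (7.29-fold) completed the 10 that rose most. NTSR1 and IGF2BP3 were each detected on 1 of 3 control arrays.

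Among genes that fell, HAPLN1, which links hyaluronan to proteoglycans, and was detected on 2 of 3 KLF2 siRNA arrays, fell 9.61-fold (log2 7.36 ± 0.61 against 10.63 ± 0.17, SD, n = 3; adjusted p = 5.55e-05). The potassium channel gene KCNH1 (at least 5.16-fold), MIX23 (at least 3.47-fold) and TENT5B (at least 3.22-fold) were not well above background on any KLF2 siRNA array. The growth factor genes NRG1 and PDGFD fell 5.15-fold and 4.72-fold. ANK2, which anchors membrane proteins to the cytoskeleton, fell 4.85-fold, MTX1 of the mitochondrial outer membrane 4.84-fold, the antisense RNA VLDLR-AS1, detected on 1 of 3 KLF2 siRNA arrays, 4.70-fold and the selenoprotein gene SELENON 4.64-fold.

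Of 52 measured interferon response genes, 39 rose and 2 fell with KLF2 siRNA, and 40 rose and 2 fell when adjusted over the list alone. Their median change was 0.96 on the log2 scale, or 1.94-fold, with a camera adjusted p = 3.46e-18, and adjusted p = 0.137 with an estimated correlation. IFIT3 rose 7.26-fold, CXCL10 5.20-fold and ISG20, an exonuclease, 2.57-fold. Of 39 NF-kB and inflammatory mediators, 19 rose and 1 fell (22 and 1 adjusted over the list alone; camera adjusted p = 4.50e-08, adjusted p = 0.00901 with an estimated correlation). VCAM1 rose 4.36-fold, CCL5 2.81-fold, CXCL8 2.78-fold and RELB 2.43-fold. Antigen presentation genes also rose, 6 of 18 with 0 lower (7 and 0 adjusted over the list alone; camera adjusted p = 0.00537, adjusted p = 0.143 with an estimated correlation), among them HLA-B (1.91-fold), HLA-E (1.75-fold) and TAP1 (1.60-fold). PSMB9 rose 1.71-fold on its brightest probe, while another probe of the gene had the opposite sign. Of 27 senescence-associated secreted factors, 11 rose and 3 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.00553, adjusted p = 0.137 with an estimated correlation). The hormone gene STC1 rose 5.28-fold in that list, and IGFBP5 fell 2.69-fold. Of 6 measured macrophage markers, CSF1R rose 2.06-fold and CD14 1.66-fold, while the list did not pass (camera adjusted p = 0.0765). It passed with the mean of the kept probes (adjusted p = 0.0309), without control array 1 (adjusted p = 0.0311) and without KLF2 siRNA array 3 (adjusted p = 0.0495). Of 4 measured lymphocyte and blood markers, 0 changed in limma.

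In the amino acid starvation response list, 17 of 27 genes fell and 0 rose with KLF2 siRNA (20 and 0 adjusted over the list alone), with a median of -0.58 on the log2 scale and a camera adjusted p = 7.40e-12, and adjusted p = 0.00744 with an estimated correlation. CTH of cysteine synthesis fell 3.10-fold, the amino acid transporter gene SLC7A5 2.79-fold, and PSPH and PSAT1 of serine synthesis 2.31-fold and 1.76-fold. Of 41 genes of G1/S and DNA replication, 11 fell and 0 rose (11 and 0 adjusted over the list alone; camera adjusted p = 0.000249, adjusted p = 0.114 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell 1.82-fold, TK1 1.79-fold, CHAF1B 1.73-fold and UHRF1 1.55-fold. Of 54 genes of G2/M and mitosis, 11 fell and 0 rose (12 and 0 adjusted over the list alone; camera adjusted p = 1.44e-06, adjusted p = 0.193 with an estimated correlation). FOXM1, a transcription factor of mitotic genes, fell 2.38-fold, CCNA2 1.61-fold, CDCA8 1.53-fold and TPX2 1.42-fold. Of 33 p53 targets and cell cycle arrest genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 0.000145, adjusted p = 0.0551 with an estimated correlation). The cyclin-dependent kinase inhibitor gene CDKN1C rose 3.11-fold, GDF15 2.79-fold and SESN1 1.80-fold, while GADD45B fell 2.64-fold.

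Of 17 smooth muscle contractile genes, 10 fell and 0 rose with KLF2 siRNA (11 and 0 adjusted over the list alone; camera adjusted p = 2.76e-06, adjusted p = 0.0551 with an estimated correlation), with MYL9 2.75-fold, CSRP1 2.23-fold, TGFB1I1 2.13-fold and PDLIM7 1.95-fold lower. Of 24 YAP and TEAD targets, 6 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.00235, adjusted p = 0.137 with an estimated correlation), and IGFBP3 fell 2.20-fold, F3 2.11-fold, CCN2 2.03-fold and AXL 1.84-fold. Of 39 genes of fibrillar collagens and matrix, 15 fell and 1 rose (18 and 2 adjusted over the list alone; camera adjusted p = 0.00106, adjusted p = 0.0649 with an estimated correlation). The cross-linking enzyme genes LOXL3 and LOX fell 2.17-fold and 1.71-fold, and the elastic fibre genes FBLN5 and MFAP5 2.05-fold and 1.68-fold. Basement membrane genes rose, 9 of 15 with 0 lower (10 and 0 adjusted over the list alone; camera adjusted p = 0.000763, adjusted p = 0.0551 with an estimated correlation), with the laminin genes LAMA4 and LAMA5 2.22-fold and 1.94-fold higher and the collagen genes COL4A1 and COL18A1 1.56-fold and 1.54-fold higher. The lysosome and autophagy list shifted upward with 7 of 27 genes higher and 1 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.0111, adjusted p = 0.258 with an estimated correlation). NEU1 rose 1.93-fold, CTSA 1.74-fold and ULK1 1.31-fold, while ATG5 fell 1.63-fold.

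Stromal cell surface markers and NOTCH genes passed the set test by a smaller margin. Of 20 stromal cell surface markers, 6 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0406, adjusted p = 0.137 with an estimated correlation), among them SUSD2 (2.37-fold), CD59 (1.69-fold) and ANPEP (1.62-fold). That call was lost with array quality weights (adjusted p = 0.0624), without KLF2 siRNA array 2 (adjusted p = 0.0839) and without KLF8 siRNA array 1 (adjusted p = 0.0541). Of 16 NOTCH signalling genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0292, adjusted p = 0.185 with an estimated correlation). The ligand gene DLL1 rose at least 1.50-fold and NOTCH1 1.69-fold, while HES1 fell 1.60-fold and LFNG, whose probes disagreed in sign, 1.87-fold on its brightest probe. This call was lost without control array 3 (adjusted p = 0.0531), KLF2 siRNA array 1 (adjusted p = 0.0989), KLF2 siRNA array 2 (adjusted p = 0.0858) or KLF2 siRNA array 3 (adjusted p = 0.0602).

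Fat cell genes went both ways with KLF2 siRNA. Of 26 adipogenesis genes, 6 rose and 6 fell (7 and 7 adjusted over the list alone), without a shift of the list (camera adjusted p = 0.819). PPARG, the nuclear receptor that drives fat cell differentiation, fell 2.00-fold (log2 10.96 ± 0.02 against 11.97 ± 0.04, SD, n = 3; adjusted p = 7.21e-05), and PLIN2, which coats lipid droplets, rose 1.43-fold. In the list written as anti-adipogenic regulators, 2 of 14 genes rose and 2 fell (2 and 2 adjusted over the list alone). Its member DKK1, a WNT antagonist gene, was 2.71-fold lower. Membership of the list does not show which way a gene acts on fat cell differentiation. In the osteogenesis list 3 of 17 genes rose and 2 fell (4 and 3 adjusted over the list alone), with BMP2 6.28-fold higher and OMD at least 3.03-fold lower. In the chondrogenesis list 2 of 9 rose and 4 fell (2 and 4 adjusted over the list alone), with COL11A1 2.62-fold lower. KLF10 fell 2.19-fold, and it and KLF2 were the 2 of 14 measured KLF family genes that changed. Of 27 matrix proteases and inhibitors, 10 rose and 4 fell (10 and 5 adjusted over the list alone; camera adjusted p = 0.0678), with the proteases MMP9 7.07-fold and MMP11 6.74-fold higher. That list passed with median scaling (adjusted p = 0.0129), no detection filter (adjusted p = 0.0167), the mean of the kept probes (adjusted p = 0.0151), only the 2 groups compared (adjusted p = 0.0484), trend and robust spread (adjusted p = 0.0347) and without KLF8 siRNA array 3 (adjusted p = 0.0473). Of 29 immediate early genes, 11 rose and 4 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.0541). It passed with no detection filter (adjusted p = 0.0126), the mean of the kept probes (adjusted p = 0.0352), only the 2 groups compared (adjusted p = 0.0484) and trend and robust spread (adjusted p = 0.042). It also passed without control array 1 (adjusted p = 0.0411), control array 3 (adjusted p = 0.0455), KLF2 siRNA array 3 (adjusted p = 0.0341) or KLF8 siRNA array 3 (adjusted p = 0.0473). Changes in hypoxia and glycolysis genes, a list that did not pass camera, included HK2 (3.57-fold) and ANGPTL4 (3.31-fold on its brightest probe, with another probe of opposite sign). Of 17 genes known as KLF2 targets in endothelium, 4 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.707). CHAC1, detected on 2 of 3 KLF2 siRNA arrays, fell 3.58-fold and TRIB3 1.68-fold in the unfolded protein response list. Of 66 cytosolic ribosomal protein genes, 2 fell and 0 rose (2 and 0 adjusted over the list alone), and of 44 oxidative phosphorylation genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone).

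In all, 15 of 41 tested lists shifted with KLF2 siRNA, 9 upward and 6 downward, and 2 of them, the NF-kB and amino acid starvation lists, passed with an estimated correlation. The estimate was 0.34 for the interferon list and 0.16 for G2/M and mitosis. For stromal cell surface markers (-0.032) and basement membrane (-0.026) it lay below the preset 0.01, and the adjusted p still rose. A call lost in that test therefore does not by itself show that the genes of a list are correlated. The list median differed in sign from the test in 5 lists, none of which passed. With each array scaled to the same median in place of quantile normalization, 1341 genes changed, 644 higher and 697 lower.

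**Figure D2:**
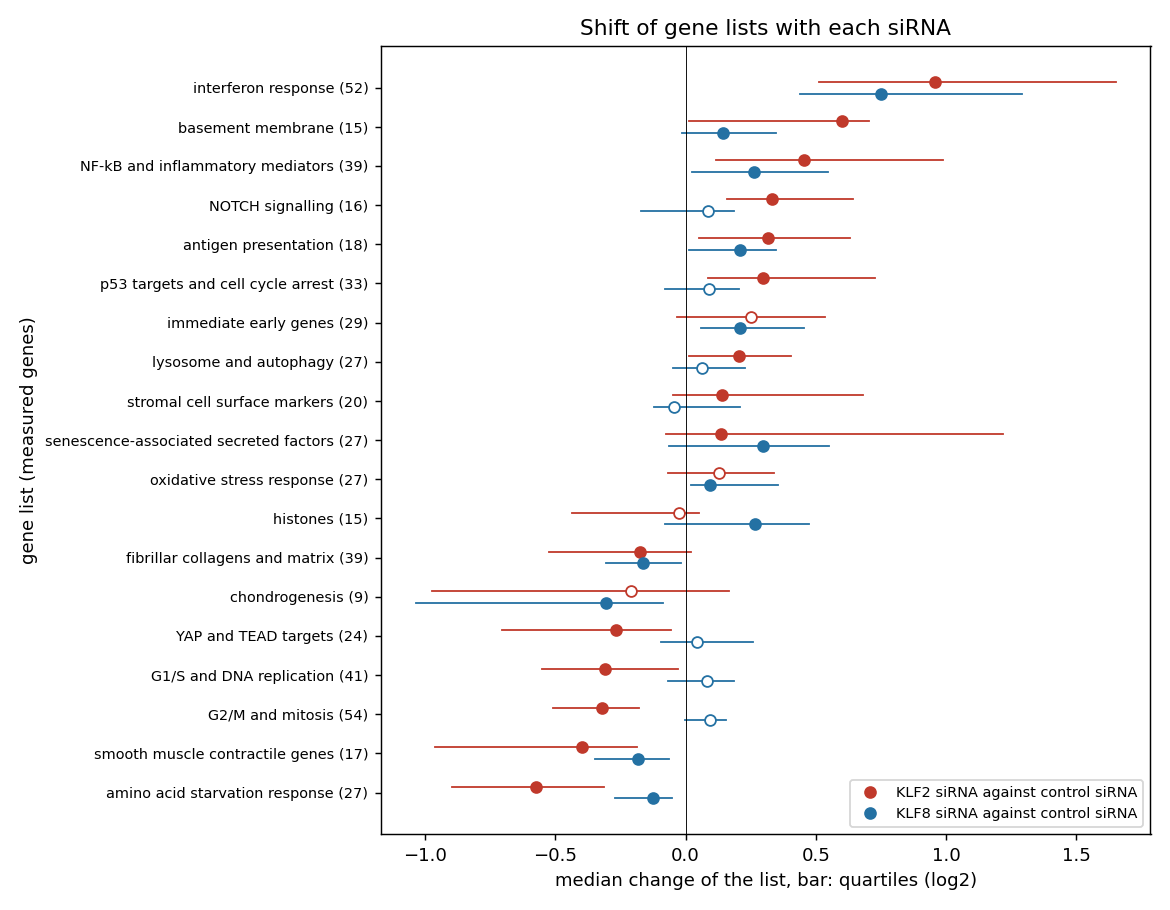
Median log2 change (horizontal axis) of each gene list that passed the set test for at least 1 siRNA, with the number of measured genes in brackets (vertical axis). Red is KLF2 siRNA and blue KLF8 siRNA, each against control siRNA; bars span the quartiles of the list, and filled points passed camera at an adjusted p under 0.05. The interferon response list has the highest medians, 0.96 and 0.75, and the amino acid starvation list the lowest median with KLF2 siRNA, -0.58.

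The comparison of KLF8 siRNA with control siRNA gave fewer changes. Of 52 interferon response genes 28 rose and 0 fell (list adjusted p = 0.0846 with an estimated correlation). Of 12030 genes, 540 changed, 328 higher and 212 lower, and 129 changed at least 2-fold (98 higher, 31 lower). In 22.0% of genes the arrays of the 2 groups did not overlap, against 10% by chance. OAS2, an antiviral sensor of double-stranded RNA, rose most, 5.49-fold (log2 12.25 ± 0.56 against 9.79 ± 0.27, SD, n = 3; adjusted p = 0.00327). NPTX1 rose 5.40-fold (9.73 ± 0.07 against 7.30 ± 0.44; adjusted p = 0.000713) and CCL7 4.58-fold (11.09 ± 0.10 against 8.90 ± 0.15; adjusted p = 0.000179). NTSR1 (4.55-fold), KYNU (4.33-fold), HERC5 (4.27-fold), IFIT3 (4.15-fold), CXCL10 (3.98-fold), the glycosyltransferase gene GCNT3 (3.96-fold) and the antiviral GTPase gene MX1 (3.95-fold) followed. MYH14, a non-muscle myosin, fell at least 2.39-fold (log2 6.91 ± 0.46 against 8.50 ± 0.40, SD, n = 3; adjusted p = 0.014), the hedgehog ligand gene DHH at least 1.80-fold and PCP4 at least 1.36-fold, each not well above background on any KLF8 siRNA array. KLHL28 fell 2.80-fold, NETO1 2.67-fold, LRRC15 2.63-fold, PDGFD 2.61-fold, the actin regulator gene ENAH 2.50-fold, DZIP1 2.47-fold and HOXD1 2.45-fold.

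Of 52 interferon response genes, 28 rose and 0 fell with KLF8 siRNA (42 and 0 adjusted over the list alone), with a median of 0.75 on the log2 scale, or 1.68-fold (camera adjusted p = 1.68e-30, adjusted p = 0.0846 with an estimated correlation). Of 39 NF-kB and inflammatory mediators, 6 rose and 0 fell (14 and 1 adjusted over the list alone; camera adjusted p = 1.25e-05, adjusted p = 0.0295 with an estimated correlation), and IRAK2 rose 2.05-fold, CXCL2 1.91-fold, CXCL5 1.86-fold and CXCL8 1.78-fold. Of 29 immediate early genes, 6 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 1.25e-05, adjusted p = 0.0295 with an estimated correlation), with ETV4 at least 1.87-fold, FOS 1.87-fold, SPRY4 1.43-fold and JUN 1.38-fold higher. Senescence-associated secreted factors rose in 5 of 27 genes with 0 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.00142, adjusted p = 0.0848 with an estimated correlation), STC1 by 1.68-fold. Antigen presentation genes rose in 2 of 18 with 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.00718, adjusted p = 0.184 with an estimated correlation), namely PSMB9 (1.63-fold) and HLA-B (1.47-fold). Of 27 oxidative stress genes, AKR1B10 rose 2.20-fold and the metallothionein gene MT1G 1.48-fold, 2 higher and 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 0.00112, adjusted p = 0.0614 with an estimated correlation). Of 6 measured macrophage markers, 0 changed.

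Histone genes rose with KLF8 siRNA, 4 of 15 with 0 lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.00563, adjusted p = 0.204 with an estimated correlation). H4C8 rose 1.86-fold, H2AC6 1.81-fold, H2BC5 1.61-fold and H2BC12 1.32-fold. Basement membrane genes rose in 3 of 15 with 0 lower (3 and 0 adjusted over the list alone; camera adjusted p = 0.012, adjusted p = 0.0848 with an estimated correlation), with LAMA1 1.89-fold, COL4A1 1.63-fold and LAMB3 at least 1.61-fold higher. That call was lost without KLF8 siRNA array 2 (adjusted p = 0.0984) and without the detection filter (adjusted p = 0.134). Cartilage genes fell, 4 of 9 with 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 0.000158, adjusted p = 0.0739 with an estimated correlation), namely HAPLN1 (2.29-fold), COL11A1 (2.14-fold), PRG4 (2.05-fold) and MATN3 (1.68-fold). Of 39 genes of fibrillar collagens and matrix, 5 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.000167, adjusted p = 0.0499 with an estimated correlation). LOX fell 1.48-fold, FBN1 1.37-fold and THBS1 1.34-fold, and LOXL4 rose 1.45-fold. Of 27 amino acid starvation genes, CTH fell 1.33-fold, 1 lower and 0 higher (1 and 0 adjusted over the list alone), with a list median of -0.12 (camera adjusted p = 0.000436, adjusted p = 0.0499 with an estimated correlation). The list of 17 smooth muscle contractile genes shifted downward with 0 genes past the threshold (5 lower and 0 higher adjusted over the list alone; camera adjusted p = 0.000705, adjusted p = 0.0848 with an estimated correlation). MYL9, for example, differed by -0.40 (adjusted p = 0.118).

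PPARG rose 1.55-fold with KLF8 siRNA (log2 12.59 ± 0.06 against 11.97 ± 0.04, SD, n = 3; adjusted p = 0.00459), and the fatty acid transporter gene CD36 rose 1.97-fold. They belonged to 26 adipogenesis genes of which 3 rose and 0 fell (5 and 2 adjusted over the list alone), without a shift of the list (camera adjusted p = 0.229). Of 17 osteogenesis genes, 2 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.711), with SPP1 2.64-fold and TNFRSF11B 2.38-fold higher. ANGPTL4 rose 3.23-fold on its brightest probe, with another probe of opposite sign. Of 22 genes of the epithelial-mesenchymal transition or linked to KLF8, 0 rose and 2 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.213). WNT5A and SFRP2 fell 1.42-fold and 1.56-fold. HSPA5, the main chaperone of the endoplasmic reticulum, fell 1.82-fold. It was the 1 gene of 24 in the unfolded protein response list that changed. The median of that list was 0.07 on the log2 scale, and the list did not pass (camera adjusted p = 0.213). Of the cell cycle genes, E2F2 rose 2.25-fold and CDC25B 1.47-fold, 1 of 41 genes of G1/S and DNA replication and 1 of 54 genes of G2/M and mitosis (1 and 1 adjusted over the list alone). These lists did not pass camera (adjusted p = 0.213 and 0.152), but passed without control array 1 (adjusted p = 0.0354 and 0.0024), and the second also without KLF8 siRNA array 3 (adjusted p = 0.0421). Of 66 cytosolic ribosomal protein genes and 44 oxidative phosphorylation genes, 0 changed in limma (0 and 0 adjusted over the list alone).

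In all, 12 of 41 lists shifted with KLF8 siRNA, 8 upward and 4 downward, and 4 passed with an estimated correlation. The count of 540 changed genes fell to 223 with median scaling (162 higher and 61 lower, 72.6% higher against 60.7%) and to 358 with a fit of the 2 groups alone. It was 301 without control array 1, 263 without control array 2, 239 without control array 3 and 288 without KLF8 siRNA array 3.

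The direct comparison asked where the effects of the 2 siRNAs differ from each other. Of 12030 genes, 2007 differed, 1008 higher and 999 lower with KLF2 siRNA, and 372 by at least 2-fold. In 33.9% of genes the arrays of the 2 groups did not overlap, against 10% by chance. CYTL1, a secreted factor of cartilage, was 9.62-fold higher with KLF2 siRNA (log2 10.91 ± 0.10 against 7.65 ± 0.47, SD, n = 3; adjusted p = 7.91e-05), MMP9 9.33-fold, the iron exporter gene SLC40A1 6.93-fold and MMP11 5.48-fold. F13A1 was also higher (log2 9.44 ± 0.18 against 6.90 ± 0.25, SD, n = 3; adjusted p = 3.43e-05). With KLF8 siRNA, CYTL1 and SLC40A1 were detected on 2 of 3 arrays and F13A1 on 1 of 3. KLHL4 was at least 3.27-fold lower (log2 6.65 ± 0.29 against 9.01 ± 0.31, SD, n = 3; adjusted p = 0.000221), KCNH1 at least 2.85-fold, TNFRSF9 4.99-fold, VLDLR-AS1 4.87-fold and SELENON 4.68-fold. With KLF2 siRNA, TNFRSF9 was detected on 2 of 3 arrays and VLDLR-AS1 on 1 of 3.

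Of 27 amino acid starvation genes, 15 were lower and 0 higher with KLF2 than with KLF8 siRNA (16 and 0 adjusted over the list alone; camera adjusted p = 2.53e-09, adjusted p = 0.0146 with an estimated correlation). Of 54 genes of G2/M and mitosis, 17 were lower and 0 higher (25 and 0 adjusted over the list alone; camera adjusted p = 5.36e-10, adjusted p = 0.123 with an estimated correlation), and of 15 histone genes, 9 were lower and 0 higher (9 and 0 adjusted over the list alone; camera adjusted p = 0.000632, adjusted p = 0.123 with an estimated correlation). Of 27 matrix proteases and inhibitors, 8 were higher and 3 lower with KLF2 siRNA (9 and 3 adjusted over the list alone; camera adjusted p = 0.0395, adjusted p = 0.123 with an estimated correlation). Of 6 macrophage markers, 2 were higher and 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.0306, adjusted p = 0.123 with an estimated correlation). The interferon response list passed camera at the preset correlation (adjusted p = 0.0306). In it 7 of 52 genes were higher and 2 lower with KLF2 siRNA (9 and 2 adjusted over the list alone), where 16.7% of all genes differed. It did not pass camera with an estimated correlation (adjusted p = 0.65) or fry (adjusted p = 0.21), so a difference of this list between the siRNAs is not settled. NF-kB and inflammatory mediators were higher with KLF2 siRNA in 10 of 39 genes and lower in 0 (camera adjusted p = 0.00103). With an estimated correlation the adjusted p of that list was 0.0798. Across 41 tested lists, 15 differed, 8 higher and 7 lower with KLF2 siRNA, and not all are printed here. Only 1, the amino acid starvation list, passed with an estimated correlation. With median scaling 906 genes differed, 349 higher and 557 lower, or 38.5% higher against 50.2%.

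The last question was how far the changes with the 2 siRNAs ran together. Across 12030 genes, which are not independent replicates, the log2 changes correlated at Pearson r = 0.52, against 0.50 (0.47 to 0.53) in 100 simulations of unchanged groups that share the control arrays. Spearman rho was 0.44 against a simulated 0.47 (0.45 to 0.49), and 65.6% of genes had the same sign against 66.7% (65.7% to 68.0%). Both lay just below the simulated range, but the simulation drew each gene independently and held no effects, so its range is too narrow. For that reason these gaps do not show less agreement than in unchanged groups. Leaving out 1 array at a time gave a standard error of 0.0704 for r, and none was computed for rho or the share with the same sign. The covariance was 0.0781 against a simulated 0.0172, a difference of 0.0608. Its standard error, from leaving out 1 array at a time, was 0.0156. Of the genes that changed with both siRNAs, 247 rose with both and 94 fell with both, where lists drawn independently would share 35.8 and 20.8, and 25 changed in opposite directions, where independent lists would give 55.3. The simulated groups shared 0 called genes. The simulated value leaves out the effects and the independent one the shared controls, and 3 control arrays are too few to give each comparison at least 2 controls of its own, so part of the excess may come from the shared controls. NPTX1, CCL7, NTSR1, KYNU, HERC5 and OAS2 were among the 10 genes that rose most with each siRNA. PPARG was lower with KLF2 siRNA and higher with KLF8 siRNA, a difference of -1.63 on the log2 scale between the siRNAs (adjusted p = 3.43e-05).

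**Figure D3:**
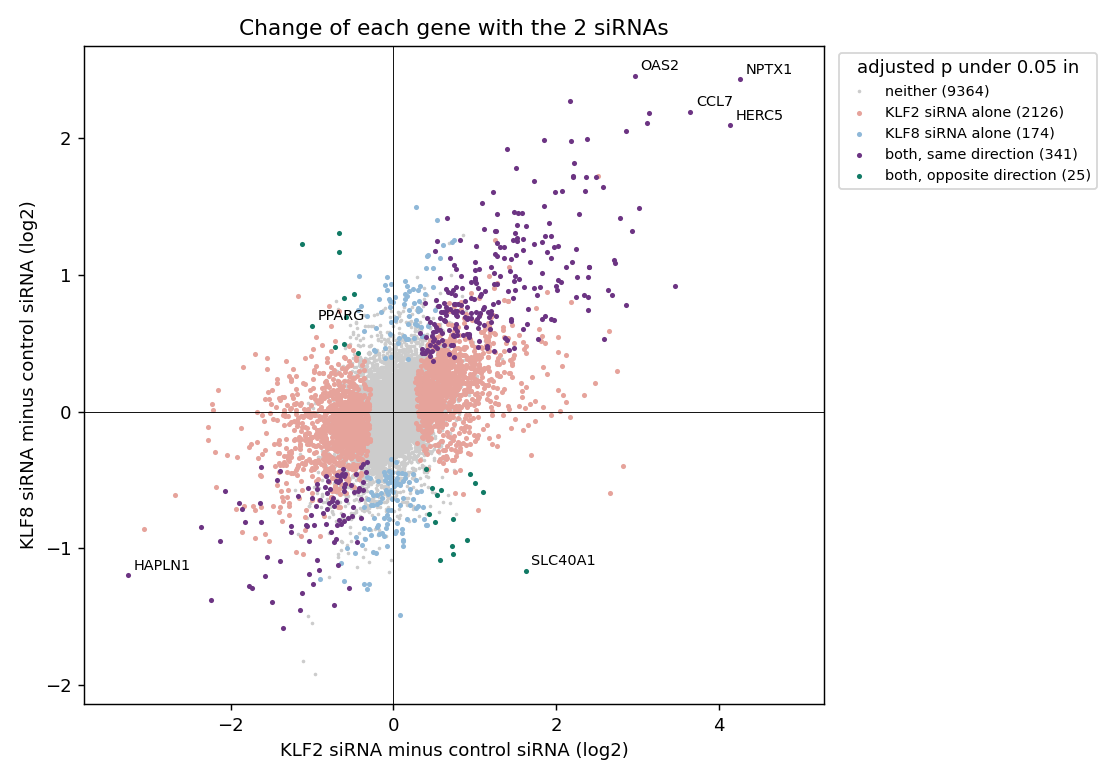
Log2 change of each of 12030 genes with KLF2 siRNA (horizontal axis) and with KLF8 siRNA (vertical axis), each against control siRNA. Colours mark genes that passed an adjusted p under 0.05 with neither, either or both siRNAs, and 341 genes passed in both with the same direction against 25 with opposite directions, among them PPARG and SLC40A1.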

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

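Of the tests below, those on the interferon list, on detection of KLF8, on the genes further from control with KLF2 siRNA, and on scaling and chance for the amino acid starvation list were chosen only after the result was seen. The results given here are unnamed probes that changed, genes that changed in opposite directions with the 2 siRNAs, and lists that differed between the siRNAs and for which, against control siRNA, both the medians and the directions of the set test were opposite. Among 5210 detected probes without a listed gene, 467 changed with KLF2 siRNA (203 higher, 264 lower) and 54 with KLF8 siRNA (28 higher, 26 lower). These were 8.96% and 1.04% of them, lower shares than the 16.8% and 2.80% of named probes. Between KLF2 and KLF8 siRNA the log2 difference was -1.84 for E2F2, 1.19 for MATN3 and -1.63 for PPARG. The median of the gene differences between KLF2 and KLF8 siRNA was -0.34 for G1/S and DNA replication, -0.41 for G2/M and mitosis, -0.38 for YAP and TEAD targets, -0.24 for the unfolded protein response, -0.58 for histones and 0.45 for the 6 macrophage markers. In that comparison their camera adjusted p was 2.15e-06, 5.36e-10, 3.37e-05, 0.00528, 0.000632 and 0.0306, and 0.0798, 0.123, 0.0798, 0.0798, 0.123 and 0.123 with an estimated correlation. Against control siRNA the unfolded protein response (camera adjusted p = 0.135 and 0.213) and the macrophage markers (0.0765 and 0.778) passed with neither siRNA, G1/S, G2/M and YAP and TEAD targets did not pass with KLF8 siRNA (0.213, 0.152 and 0.33), and histones did not pass with KLF2 siRNA (0.242).

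Of 52 interferon response genes, 39 rose with KLF2 siRNA and 28 with KLF8 siRNA (list adjusted p = 0.137 and 0.0846 with an estimated correlation). Scaling could produce such a shift, but under 3 other scalings the lowest list median relative to all genes was 0.67 on the log2 scale. By the rule set for it, that argues against scaling. Among the 3, only median scaling was not a form of quantile normalization, so the test rests mainly on it. The 3 control arrays stood apart with an exact permutation p = 0.0119 over 84 choices of 3 arrays, the smallest p possible, but the list had been picked for that difference, so a chance level of these arrays stayed open. A reaction to the siRNA reagents rather than to loss of KLF2 or KLF8 may also raise these genes. With 1 reagent group per target and a median gene difference of 0.15 between the siRNAs, that hypothesis and an effect of target loss cannot be told apart.

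Genes changed with KLF8 siRNA although the KLF8 probe was detected on 0 of 9 arrays, so whether the transcript fell could not be seen. A response that KLF2 siRNA gives to the same extent might account for them. Of 540 genes, 171 (31.7%) also differed from KLF2 siRNA in the direction of the KLF8 siRNA change. Another 101 (18.7%) differed by lying further from control with KLF2 siRNA. Both shares passed the limit of the rule, but no share expected under an equal response was computed. The KLF8 siRNA arrays that chose the 540 genes also enter the direct comparison, which can raise the count of 171, so that count does not decide. It does not raise the count of 101, which argues against an equal response for those 101 genes as a set. The rule for that count was written after the result was seen, and single genes are not settled. Of the other 268 genes, 100% had the same sign with KLF2 siRNA, which follows from how the genes were divided and leaves the hypothesis open for them.

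Amino acid starvation response genes fell with KLF2 siRNA. Scaling could lower them, but the list median relative to all genes stayed at -0.57 or further from 0 under 3 other scalings. By the rule set for it, that argues against scaling, though here too the test rests mainly on median scaling. The exact permutation p = 0.0119 over 84 choices was computed on a list picked for its difference, so chance among the arrays stayed open. ATF4 encodes the transcription factor that drives many of these genes, and a lower ATF4 transcript level is a hypothesis for their fall. The ATF4 transcript differed by 0.10 (-0.33 to 0.53, 2 standard errors; adjusted p = 0.803), and the lower end reached past -0.29, 0.5 of the list median, so the hypothesis stayed open.

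Each comparison was also run on the 10 splits of its 6 arrays into 3 and 3, too few for a share under 0.05. The real split, 1 of 10, gave 2492 genes with KLF2 siRNA, 540 with KLF8 siRNA and 2007 in the direct comparison. The highest other split gave 0 in each. Every other split mixes the 2 groups, so a real group difference adds to its spread, and the 0 says little about chance. For gene lists the real split gave 15 with KLF2 siRNA and 12 with KLF8 siRNA, and the highest other split 10 and 6.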

How the results depend on the processing

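No alternative below was chosen after the result was seen. With the 2-fold threshold 584 genes changed with KLF2 siRNA, 129 with KLF8 siRNA and 372 differed directly, and with median scaling 1341, 223 and 906. A fit of the 2 groups alone gave 358 genes with KLF8 siRNA. Without 1 array that count ran from 239 (control array 3) to 517 (KLF2 siRNA array 2), with 301 without control array 1, 263 without control array 2 and 288 without KLF8 siRNA array 3. Lists shifted numbered 2 with KLF2 siRNA and 4 with KLF8 siRNA with an estimated correlation, and 29 with KLF2 siRNA with fry. Replicate numbers did not pair the samples: 2 of 9 same-numbered pairs had a correlation of deviations over 0.1 (-0.37 to 0.24), and 3 of 9 arrays correlated best with their own number. With a replicate block 311 genes changed with KLF8 siRNA (208 higher, 103 lower), and the stromal cell surface marker list did not pass with KLF2 siRNA (adjusted p = 0.0578). Of named genes that passed, 99 of 116 with KLF2 siRNA, 35 of 79 with KLF8 siRNA and 10 of 10 in the direct comparison passed under each of 19 alternatives that measured them. No call of a named gene or of a list tested against control siRNA turned direction in these alternatives, but with median scaling the balance of calls turned with KLF2 siRNA (644 higher, 697 lower) and moved in the direct comparison (349 higher, 557 lower). The chip was not used as a block, since no chip is named in the sources used here, and the series value table, identical to the normalized table, was not run again.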

Other observations

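The gene families here were chosen after the data had been examined, 29 in all, and were tested with camera. Of 16 cytosolic aminoacyl-tRNA synthetase genes, whose products charge transfer RNAs, 7 fell and 0 rose with KLF2 siRNA, with a median of -0.33 (adjusted p = 0.00412, adjusted p = 0.33 with an estimated correlation). Of the 16, 5 were also in a list described above. WARS1 fell by 0.71 and MARS1 by 0.60 on the log2 scale, each chosen after its values were seen. With KLF8 siRNA 0 of these genes changed, and the family was lower with KLF2 than with KLF8 siRNA (adjusted p = 0.0206, adjusted p = 0.443 with an estimated correlation).

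With KLF8 siRNA 354 zinc finger ZNF genes had a median of -0.11, with 8 lower and 1 higher (adjusted p = 0.000232, adjusted p = 0.202 with an estimated correlation). Over all genes 4.49% changed, a larger share than among these. The guanylate-binding and IFI family also passed camera, with 5 of 13 genes higher and 0 lower (adjusted p = 0.000153, adjusted p = 0.202 with an estimated correlation). Of its 13 genes, 7 were also in a list. Of 12 TNF receptor superfamily genes, TNFRSF11B and TNFRSF21 rose with KLF8 siRNA (adjusted p = 0.00341 for the family, adjusted p = 0.202 with an estimated correlation). Among genes with opposite changes, each chosen after its values were seen, SLC40A1 rose by 1.63 with KLF2 siRNA and fell by 1.16 with KLF8 siRNA on the log2 scale. HNRNPU, an RNA-binding protein gene, rose by 0.73 and fell by 1.04, and AFP, the alpha-fetoprotein gene, fell by 0.67 and rose by 1.31.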
